A study of Danio rerio with 8 samples.

How the data were processed

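The deposited data were bulk RNA-seq read counts from cells sorted by fluorescence from the pancreas of zebrafish at 30 days post fertilization. The fish carried an EGFP reporter for the somatostatin gene sst1.1 and a fluorescent reporter under the insulin promoter. Per the labels, 3 libraries came from cells positive for both reporters (sst1.1+ins+), 3 from cells positive for the sst1.1 reporter alone (sst1.1+) and 2 from cells positive for the insulin reporter alone (ins+). Cells were sorted into lysis buffer and cDNA was made by Smart-Seq2, a full-length protocol without molecular identifiers. The labels do not say whether replicates came from separate animals, pools or sorts, so p-values measure only the spread between these libraries, which may be technical.

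The authors deposited raw read counts per gene. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned with HISAT2 to the GRCz11 assembly and assigned to exons with featureCounts. Tool versions, the annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Reads shared between near-identical copies (such as hsp70.1, hsp70.2 and hsp70.3) or between overlapping genes cannot be apportioned, and the values of such genes are uncertain. The table held 32046 rows, of which 31953 were zebrafish genes, 92 were ERCC spike-in controls and 1 was EGFP. The ERCC and EGFP rows stayed out of library totals and tests. Their shares were 0.0145 to 0.0501% and 0.0200 to 0.810% of each library. Gene totals ran from 16948429 to 30374029 counts per library, and 3 counts, taken as the floor, corresponded to 0.101 to 0.176 CPM (counts scaled to the total, the unit of all abundances here). Intervals and floors cover counting error only. No genome was used here, so no coordinates are given. Of the 31953 gene rows, 26121 had their identifier in the names table at hand. Gene names are those of the deposited table, where hhex is written HHEX. Where a listed symbol stood on several rows, the row with the most counts was taken.

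Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes passing the default expression filter by group numbered 16418. TMM factors, 1 mean per group over all 8 libraries (5 residual degrees of freedom) and the quasi-likelihood F-test gave log2 fold changes, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Standard errors (SE) of log2 fold changes are the fold change divided by the square root of the F statistic. Values are CPM on TMM-scaled totals, as mean ± SD over libraries. A gene was called above or below both single-positive groups when it passed in both comparisons with the same sign. For genes called between ins+ and sst1.1+ with at least a 2-fold difference, the position of sst1.1+ins+ was its mean log2 CPM (prior count 2) on a scale where sst1.1+ is 0 and ins+ is 1. The 26 gene lists (markers of islet and other cell types, and pathways) were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with the correlation estimated per list. Lists with fewer than 4 tested genes (23 had enough) were only counted. Within a list, calls were counted over all genes tested and adjusted over the list alone.

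The genes to be named were fixed by rule before the data were examined: the 10 largest rises and 10 largest falls per comparison past 0.05, with non-overlapping CPM, a mean of at least 20 CPM in the higher group and a gene name that is not an identifier, clone or locus code, up to 4 members of each list with the smallest p, and ins, sst1.1, sst1.2, sst2, pdx1, hhex, mnx1 and gcga. Groups, lists, the design and most alternatives were also fixed then. A fold against a group at 0 counts in all libraries was computed against the floor of 3 counts per library. The alternatives were RLE scaling, library totals, DESeq2 1.42.0, limma-voom with quality weights, other filters, a replicate block, 2-group fits, totals without hormone and mitochondrial genes, and each library left out in turn. After the data were seen, fits with all libraries thinned to the smallest total, counts without stress list genes, and fits that gave each comparison its own libraries of the shared group were added. In those fits a single library was assumed to vary like the other groups.

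Tested on counts simulated from the libraries' own means, totals and dispersions over 16418 genes, edgeR recovered 6, 24, 28 and 39 of 50 genes changed 2-, 4-, 8- and 16-fold for ins+ against sst1.1+, with 13 false calls. For sst1.1+ins+ it recovered 5, 24, 33 and 41 against sst1.1+ (7 false calls) and 4, 22, 33 and 40 against ins+ (10 false calls). A list of 25 genes shifted 2-fold for ins+ against sst1.1+ was called and 0 of the other lists were. The simulated genes varied independently of each other, while the correlation estimated for the real cell cycle list was 0.549 in that comparison. The simulation therefore does not bound false list calls among correlated genes. Figures were drawn with matplotlib 3.10.9.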

Results

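Gene expression was profiled in 8 libraries of sorted zebrafish pancreatic cells. The 3 sst1.1+ libraries held 23425079 to 30374029 gene counts, the 3 sst1.1+ins+ libraries 24234927 to 24504469 and the 2 ins+ libraries 16948429 and 19861081. Counts were seen for 16643 ± 189 genes in sst1.1+ (SD, n = 3), 16882 ± 861 in sst1.1+ins+ (n = 3) and 15268 ± 489 in ins+ (n = 2). ERCC spike-ins took 0.0295 ± 0.00521% of counts in sst1.1+, 0.0200 ± 0.00484% in sst1.1+ins+ and 0.0458 ± 0.00604% in ins+. Across genes, which are not independent replicates, Pearson correlations of log2 CPM ran from 0.828 to 0.874 between libraries of 1 group and from 0.781 to 0.8 between ins+ and sst1.1+. They ran from 0.815 to 0.860 between sst1.1+ins+ and sst1.1+ and from 0.807 to 0.838 between sst1.1+ins+ and ins+. Both of these ranges overlap that within groups. The 2 ins+ libraries lay at opposite ends of the second principal component (111.8 and -113.8), and the description of ins+ replicate 2, the shallowest library, gives a track number outside the run of the other 7.

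The hormone and reporter transcripts followed the sort. Insulin (ins) made up 24.8 ± 1.44% of gene counts in ins+ (SD, n = 2), 12.3 ± 1.03% in sst1.1+ins+ (n = 3) and 0.0979 ± 0.0310% in sst1.1+ (n = 3). The somatostatin gene sst1.1 made up 27.7 ± 1.94% in sst1.1+, 18.3 ± 1.76% in sst1.1+ins+ and 4.95 ± 0.854% in ins+. EGFP stood at 7528 ± 945 CPM in sst1.1+, 3412 ± 232 in sst1.1+ins+ and 239 ± 57.9 in ins+. The other somatostatin genes were not called, which leaves differences of 2-fold open: sst1.2 averaged 27600 ± 10800 CPM in sst1.1+, 28010 ± 11000 in sst1.1+ins+ and 23670 ± 349 in ins+, and sst2 averaged 13680 ± 9280, 17450 ± 9910 and 20770 ± 31.3 CPM, with adjusted p of 0.559 or more in each comparison.

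**Figure D1:**
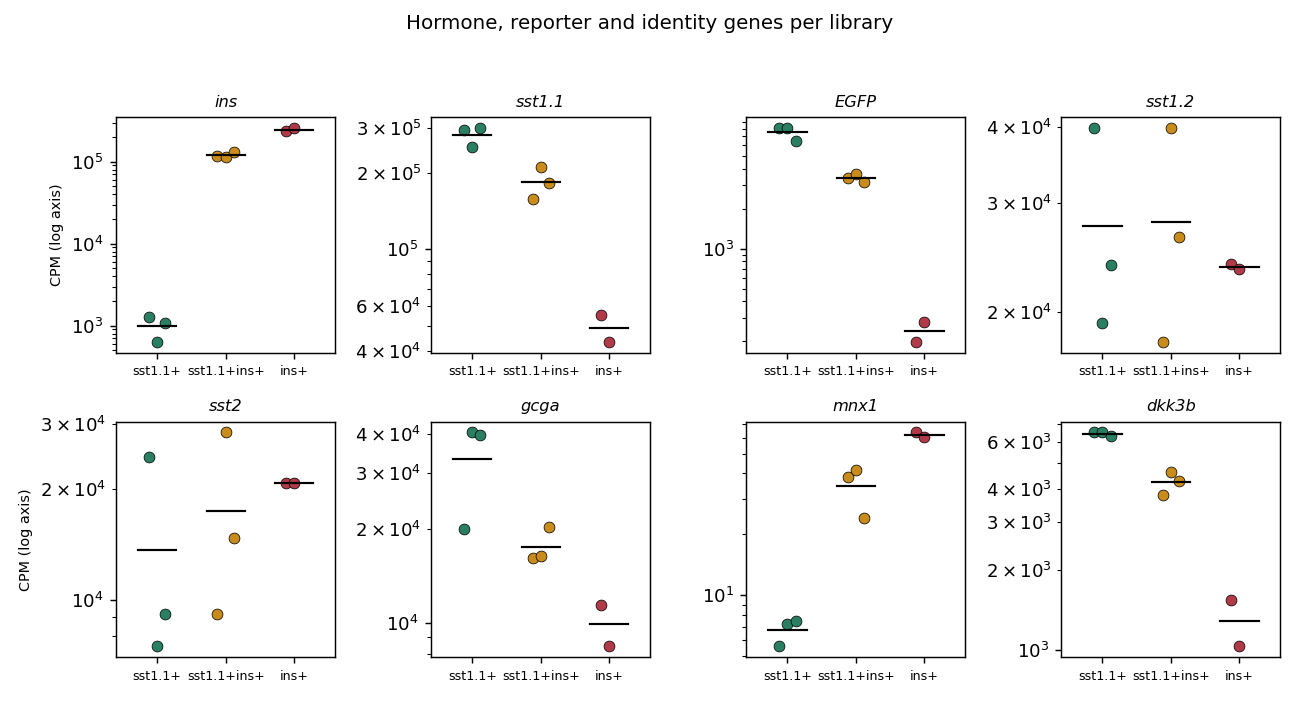
CPM (log axis) of 8 transcripts in each library, with groups on the horizontal axis, points for single libraries and bars for group means. For ins, sst1.1, EGFP, mnx1 and dkk3b the sst1.1+ins+ libraries lie between both single-positive groups, while sst1.2 and sst2 overlap.

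The first comparison asked how insulin-positive cells differ from sst1.1-positive cells. Of 16418 genes tested, 662 were called (265 higher and 397 lower in ins+), and 565 of them differed at least 2-fold. Beside ins (247-fold, log2 fold change 7.95 ± 0.26 SE, adjusted p = 4.23e-08), the largest rises in ins+ included the glucagon receptor gene gcgra, at 64.2 ± 29.9 CPM against 0.226 ± 0.221 (282-fold, adjusted p = 8.10e-05). The size of this fold rests on only 7, 0 and 10 counts in the sst1.1+ libraries. The homeobox gene nkx6.2 averaged 104 ± 38.9 CPM against 0.895 ± 0.906, and mnx1, a beta-cell transcription factor, was 9.21-fold higher (62.2 ± 2.24 against 6.76 ± 1 CPM, adjusted p = 0.000112). The calcium-binding protein gene cabp5a was 29.7-fold higher, abhd15a 29.2-fold, the glutamate receptor subunit gria3a 16.3-fold, the vesicle GTPase rab3c 15.2-fold and the GABA receptor subunit gabrb2 15.2-fold. A MAF gene listed as MAF (2 of 2) averaged 62.6 ± 14.6 against 2.41 ± 1.74 CPM. The secreted-protein gene epd averaged 169 ± 213 CPM in ins+ against 0.982 ± 0.851, a call lost in 2 of 14 alternatives (adjusted p up to 0.361).

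Among the largest falls, the sphingosine-1-phosphate receptor gene s1pr1 stood at 71.4 ± 10.9 CPM in sst1.1+ and at 0 counts in both ins+ libraries, at least 438-fold lower. The matrix gene hapln1b stood at 22.9 ± 6.95 CPM in sst1.1+ and at only 1 and 3 counts in the ins+ libraries. The complexin gene CPLX1 (2 of 2) was 28.7-fold lower. For the next genes the size of the fall rests on few counts or on 1 of the ins+ libraries, so means are given: the epithelial transcription factor elf3 (335 ± 92.8 CPM in sst1.1+, 9.03 ± 10.7 in ins+), the peptidase gene ace (37.6 ± 19.6 and 0.866 ± 0.519), the small GTPase rhoub (32.1 ± 8.87 and 1.08 ± 1.36), the integrin itga5 (23.4 ± 12.5 and 0.553 ± 0.712), adgrg1 (21.3 ± 5.63 and 0.558 ± 0.789) and filip1l (21.1 ± 6.41 and 0.294 ± 0.415). The HSP70 co-chaperone bag3 fell from 1172 ± 165 CPM in sst1.1+ to 38.4 ± 13.7 in ins+ (30.5-fold, adjusted p = 1.62e-06). The calls of itga5 and adgrg1 were lost in 6 and 7 of 14 alternatives, left-out libraries included, and named calls printed without such a count were lost in at most 1.

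Of 13 tested beta-cell genes, 5 rose and 0 fell (the count adjusted over the list alone was also 5), among them ins, nkx6.2, mnx1 and the glucose transporter slc2a2 (1.69-fold, adjusted p = 0.0120, lost in 2 of 14 alternatives). The list test was called upward (camera, adjusted p = 7.86e-13, and adjusted p = 0.0219 with an estimated correlation), with a median log2 fold change of 0.694. The beta-cell list holds ins and the delta-cell list sst1.1, and reporters of these genes defined the sort. No list test was run without them. In every comparison the p-values of these lists are therefore not independent of the sort. The pancreatic transcription factor pdx1 did not pass (1227 ± 91.4 CPM in ins+ and 1414 ± 274 in sst1.1+, adjusted p = 0.554). Of 7 delta-cell genes 3 fell (4 adjusted over the list alone): sst1.1 (5.72-fold), the secreted Wnt modulator dkk3b (4.99-fold) and the delta-cell transcription factor gene HHEX (4.27-fold, adjusted p = 0.00191). The list was called downward (adjusted p = 6.63e-08), with adjusted p = 0.0580 with an estimated correlation. Other hormone genes were also lower in ins+: gcga by 3.36-fold, gcgb by 4.24-fold (21520 ± 6690 against 5075 ± 3060 CPM, and without ins+ replicate 2 the log2 differences were 1.55 and 1.57, with adjusted p = 0.0569 and 0.0713) and pyyb, 1 of 2 tested genes listed for other hormones, by 7.77-fold (1332 ± 59.7 against 171 ± 26.2 CPM). For the alpha-cell list 2 of 7 genes fell (3 adjusted over the list alone) and the test gave adjusted p = 0.0119, against adjusted p = 0.12 with an estimated correlation. The alpha-cell regulator arxa stood at 13 ± 1.99 CPM in sst1.1+ and 2.88 ± 0.583 in ins+ (adjusted p = 0.0767).

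Immediate early and heat shock genes gave the smallest list p, though not the largest median change. Of 25 immediate early and heat shock genes, 16 fell in ins+ and 0 rose (19 fell adjusted over the list alone). The transcription factor gene atf3 was 19.2-fold lower (967 ± 97.2 CPM in sst1.1+, 50.4 ± 14.2 in ins+), jun 13.1-fold, and the heat shock genes hsp70.1 and hsp70.2, whose reads may be shared, 6.89-fold and 5.72-fold. The list gave adjusted p = 9.16e-38, and adjusted p = 0.0101 with an estimated correlation. Of 30 endoplasmic reticulum (ER) stress genes, 12 fell and 0 rose (17 and 1 adjusted over the list alone). The ER chaperones hspa5 and hsp90b1 were 7.05-fold and 5.25-fold lower, ddit3 was 5.18-fold lower and herpud1 averaged 12.9 ± 8.35 against 122 ± 5.14 CPM (adjusted p = 1.46e-16 for the list, and adjusted p = 0.0219 with an estimated correlation). Dropping the genes of the immediate early and ER stress lists from the finished result left 634 calls. No new fit was made, so this does not test whether stress affects the other genes. Library depth was also lowest in ins+, and its ERCC share highest.

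**Figure D2:**
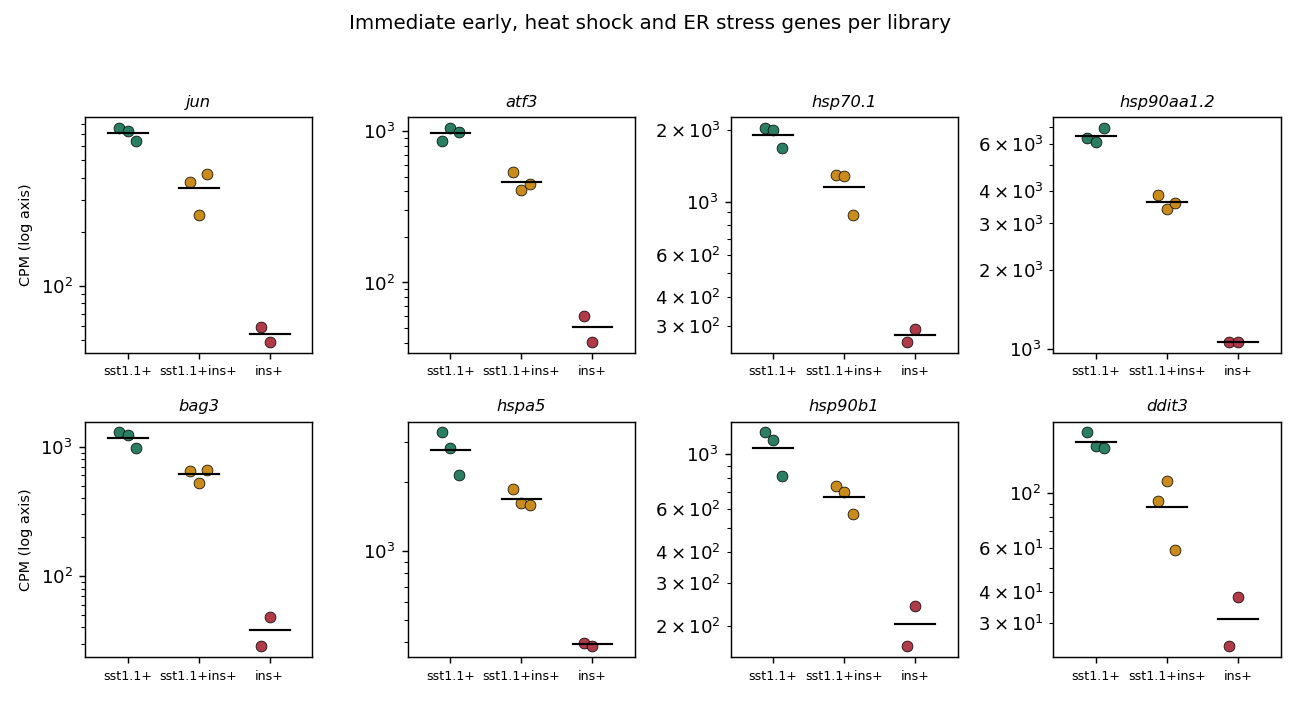
CPM (log axis) of 8 immediate early, heat shock and ER stress genes in each library, with groups on the horizontal axis, points for libraries and bars for group means. The ins+ libraries lie below all other libraries for each of the 8 genes, and the sst1.1+ means are highest.

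Secretory and channel genes went both ways. Of 20 pan-endocrine genes 4 rose and 4 fell (9 and 4 adjusted over the list alone): the carboxypeptidase cpe was 1.57-fold higher, and the granins chga, scg2a and scg2b were 3.71-fold, 3.53-fold and 2.40-fold lower (list adjusted p = 0.707). Of 31 exocytosis genes 5 rose and 2 fell (9 and 3 adjusted over the list alone), with cplx2 5.83-fold higher and syt4 3.25-fold lower (adjusted p = 0.0178 upward, and adjusted p = 0.0988 with an estimated correlation). Among 28 ion channel genes 2 rose and 2 fell, also when adjusted over the list alone: the sodium channel subunit scn3b was 3.58-fold higher and the potassium channel kcnh6a 7.28-fold lower, the latter lost in 2 of 14 alternatives (list adjusted p = 0.827, upward although the median was -0.30 and the mean -0.26). Of 16 hormone and transmitter receptors 2 rose (2 adjusted over the list alone), gcgra and vipr2 (3.35-fold), with adjusted p = 0.0233 and adjusted p = 0.12 with an estimated correlation. Of 41 endocrine transcription factors 5 rose and 3 fell (10 and 5 adjusted over the list alone), with fev 2.52-fold lower, a call lost in 2 of 14 alternatives (adjusted p = 0.0208 upward, and adjusted p = 0.0988 with an estimated correlation). Of 24 progenitor and Notch genes 1 rose, sox4a (2.55-fold), and 2 fell (2 and 6 adjusted over the list alone): notch1b, with 0 counts in ins+ (at least 34.3-fold lower), and its target class member her6 (0.486 ± 0.476 against 14 ± 6.11 CPM, list adjusted p = 0.243).

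Among metabolic and housekeeping lists, 8 of 94 oxidative phosphorylation genes fell and 1 rose (12 and 1 adjusted over the list alone): ndufa6 was 2.31-fold lower, and ndufa4l2a rose 9.36-fold, from 95.7 ± 11.7 to 896 ± 51.1 CPM, against the direction of its list (adjusted p = 0.000297 downward, and adjusted p = 0.173 with an estimated correlation). Of 77 ribosomal protein genes 4 rose (26 adjusted over the list alone), led by rpl22l1 (2.32-fold), and of 42 proteasome genes 4 fell (5 adjusted over the list alone), among them psmc4 (2.38-fold). The proteasome calls were lost in 7 (psma6l and psmc4), 9 (psmb7) and 11 (psmb11) of 14 alternatives, and the ribosomal calls in 3 (rpl22l1) to 8 (rpl5a). The ribosomal and proteasome lists were called (adjusted p = 6.46e-10 and 9.75e-07), with adjusted p = 0.406 and adjusted p = 0.222 with an estimated correlation. Of 22 glycolysis genes 1 fell, pkma (1.74-fold, lost in 6 of 14 alternatives, list adjusted p = 0.851). The 13 mitochondrially encoded genes (adjusted p = 0.0682), 32 cell cycle genes (0.186) and 22 p53 response genes (0.844) were not called as lists, and tp53inp1 of the last rose 2.68-fold while gadd45ba fell 1.85-fold, a call lost in 7 of 14 alternatives.

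Among markers of other cell types, the ductal and immune lists were called lower in ins+. Of 11 ductal and epithelial genes 5 fell (also 5 adjusted over the list alone), with krt8 at 237 ± 44.5 CPM in sst1.1+ and 101 ± 21.5 in ins+ and clu 2.89-fold lower (adjusted p = 7.86e-06, and adjusted p = 0.0914 with an estimated correlation). Of 5 immune genes cd74a fell, 5.82-fold, a call lost in 2 of 14 alternatives with adjusted p up to 0.0941 (2 adjusted over the list alone, list adjusted p = 0.0119, and adjusted p = 0.245 with an estimated correlation). No gene was called among 19 acinar (list adjusted p = 0.173), 9 mesenchymal (0.243), 5 hepatocyte (0.551), 2 erythrocyte or 1 endothelial genes tested.

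The count of 662 was 436, 420 and 330 without sst1.1+ replicate 1, sst1.1+ replicate 2 and ins+ replicate 2, and 412 when only the libraries of both groups were fitted. It was 1677 with DESeq2, which made 78 false calls in simulated counts against 13 by edgeR, and 1276 without a low-count filter. Limma-voom (5 false calls) called 353 genes higher and 262 lower, the opposite balance. In these simulated counts, drawn with dispersions from edgeR, DESeq2 recovered more changed genes than edgeR (9, 29, 29 and 40 of 50 at 2-, 4-, 8- and 16-fold). Limma-voom recovered fewer (4, 18, 21 and 27).

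The second comparison asked what sets double-positive cells apart from sst1.1+ cells. In sst1.1+ins+ 29 genes rose and 5 fell, 34 in all. The largest rises were ins (122-fold, log2 fold change 6.93 ± 0.25 SE, adjusted p = 9.99e-08), gcgra (27.6 ± 7.77 against 0.226 ± 0.221 CPM, the latter from 7, 0 and 10 counts), nkx6.2 (44.7 ± 3.19 against 0.895 ± 0.906 CPM) and cabp5a (33.2-fold). Next came abhd15a (14.7-fold, adjusted p = 1.08e-05), rab3c (8.79-fold), the amino acid transporter gene slc38a11 (7.70-fold), nell2a (6.71-fold), the RNA-binding protein gene rbfox3 (6.21-fold) and the chemokine cxcl14 (5.50-fold). The genes mnx1 (5.14-fold, 34.7 ± 9.26 against 6.76 ± 1 CPM) and ndufa4l2a (4.99-fold) also rose. The named falls were smaller: keratin krt15 fell 2.87-fold (38.0 ± 3.49 against 109 ± 19.6 CPM), atf3 2.08-fold, integrin itga6b 1.95-fold and hsp90aa1.2 1.79-fold (3610 ± 215 against 6452 ± 409 CPM, adjusted p = 0.00422). The calls of rab3c and atf3 were lost in 7 of 14 alternatives, that of nell2a in 6, that of itga6b in 3 and those of krt15 and nkx6.2 in 2.

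By list, 3 of 13 beta-cell genes rose and 0 fell (6 adjusted over the list alone): ins, mnx1 and nkx6.2, with list adjusted p = 7.23e-22, and adjusted p = 0.0149 with an estimated correlation. No delta-cell gene passed (3 fell adjusted over the list alone): sst1.1 stood at a log2 fold change of -0.62 ± 0.12 SE (adjusted p = 0.0894), dkk3b at -0.60 ± 0.14 (adjusted p = 0.168) and HHEX at -0.93 ± 0.24 (adjusted p = 0.223). The delta list was called downward (adjusted p = 0.0483, and adjusted p = 0.364 with an estimated correlation), with a median of -0.10 and a mean of 0.05. Among immediate early and heat shock genes 1 of 25 fell, atf3 (9 adjusted over the list alone). The list members jun (349 ± 89.6 against 709 ± 59.3 CPM, adjusted p = 0.0669) and hsp70.3 (adjusted p = 0.0583) did not pass. The lists of immediate early and ER stress genes were called downward (adjusted p = 2.45e-09 and 3.32e-09), each with adjusted p = 0.0668 with an estimated correlation. No ER stress gene passed over all genes and 4 fell adjusted over the list alone.

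Further lists called in this comparison lost the call with an estimated correlation. Receptors were called upward (adjusted p = 0.00574, and adjusted p = 0.0928 with an estimated correlation), with gcgra the 1 of 16 that rose, and 2 adjusted over the list alone. Endocrine transcription factors were called upward (adjusted p = 0.00854, and adjusted p = 0.0928 with an estimated correlation), with 2 of 41 risen, mnx1 and nkx6.2, and 3 adjusted over the list alone. The 32 cell cycle genes were called upward with 0 single genes (adjusted p = 0.000127, and adjusted p = 0.432 with an estimated correlation). Among them stmn1a averaged 268 ± 86.2 CPM in sst1.1+ins+ and 118 ± 45.7 in sst1.1+. The mitochondrially encoded genes were called upward (adjusted p = 0.0173, and adjusted p = 0.343 with an estimated correlation). Called downward were immune genes (adjusted p = 0.000636, and adjusted p = 0.208 with an estimated correlation), oxidative phosphorylation (adjusted p = 0.00324, and adjusted p = 0.340 with an estimated correlation) and proteasome genes (adjusted p = 0.0183, and adjusted p = 0.463 with an estimated correlation). Mesenchymal genes (adjusted p = 0.0467, and adjusted p = 0.419 with an estimated correlation) and ductal genes (adjusted p = 0.0471, and adjusted p = 0.343 with an estimated correlation) were also called downward, although the mean log2 fold change of ductal genes was 0.25 because cftr had 0 counts in sst1.1+. In the immune list, cd74a averaged 27.5 ± 14.1 CPM against 109 ± 40.0 (adjusted p = 0.0916).

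All 34 genes were also called for ins+ against sst1.1+, each in the same direction. Independent lists of these sizes would share 0.468 rising and 0.121 falling genes. Unchanged groups simulated on these libraries shared at most 1 but made at most 4 calls, so they bound the overlap little. Both comparisons use the same 3 sst1.1+ libraries, too few for 2 libraries on each side, so part of the excess may come from them. In 6 fits, added after the data were seen, that gave each comparison its own sst1.1+ libraries, 13 to 27 genes were called and 12 to 25 of them were shared in direction. The count of 34 was 19 without sst1.1+ins+ replicate 3, 270 with DESeq2 (56 false calls in simulated counts against 7), 229 without a low-count filter and 79 with a filter at 10 CPM. With limma-voom (2 false calls) it was 99, of which 40 were higher and 59 lower, so the balance of rises and falls depends on the test.

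**Figure D3:**
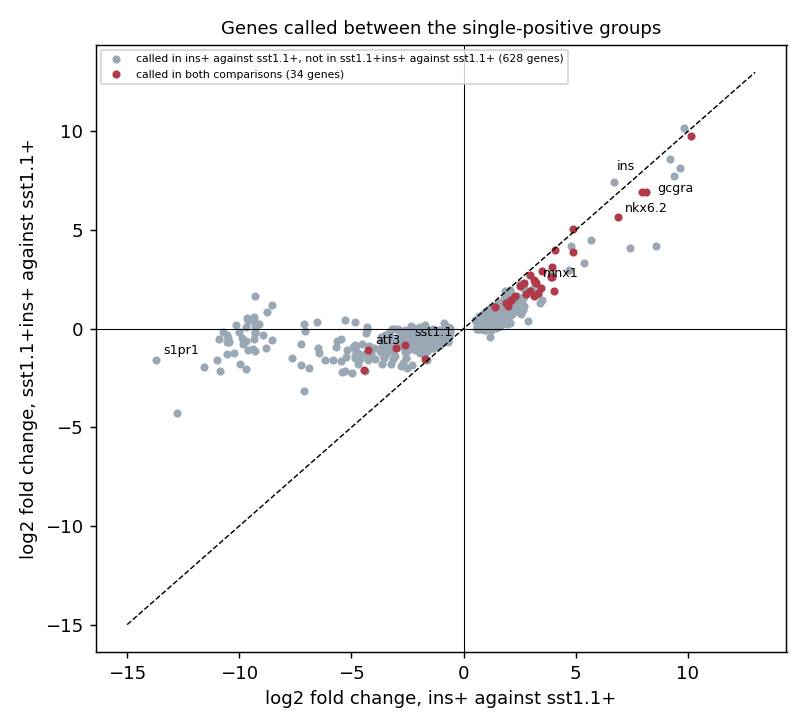
Log2 fold change of sst1.1+ins+ against sst1.1+ (vertical) plotted over that of ins+ against sst1.1+ (horizontal) for the 662 genes called between the single-positive groups, 34 of them, in red, called in both. The dashed line marks equal values, and fitted values beyond about -8 belong to genes at or near 0 counts in ins+ and are not bounds.

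The third comparison set double-positive cells against ins+ cells. In sst1.1+ins+ 124 genes were higher and 27 lower, 151 in all. The gene s1pr1 was at 24.2 ± 17.6 CPM against 0 counts (at least 148-fold higher), ace averaged 26.6 ± 10.3 against 0.866 ± 0.519 CPM, bag3 was 16-fold (615 ± 79.7 against 38.4 ± 13.7 CPM, adjusted p = 3.24e-05), the RNA-binding protein gene rbpms2b averaged 21 ± 4.22 against 1.58 ± 0.754 and the chitinase gene chia.6 22.3 ± 1.02 against 2 ± 1.33 CPM. Further rises were atf3 (9.20-fold), the syntaxin stx2b (8.27-fold), tagln2 (32.7 ± 14.4 against 4.23 ± 3.9 CPM), fam46bb (47.3 ± 12.2 against 6.58 ± 4.58 CPM) and kcnh6a (6.65-fold). The largest falls were cyclin T1 gene ccnt1 (5.05-fold), gria3a (4.28-fold), the splicing factor srsf6a (3.42-fold), shisa4 (3.06-fold), gnpda2 (2.95-fold), PKIB (2 of 2) (2.90-fold), bsg (2.85-fold), SNCG (2 of 2) (2.78-fold), the amino acid transporter slc7a8b (2.69-fold) and cbsb (2.66-fold). SNCG (2 of 2) stood at 147 ± 32.6 CPM against 407 ± 29.0. The hormone ins was 2.03-fold lower (log2 fold change -1.02 ± 0.21 SE, adjusted p = 0.0495), a call lost in 6 of 14 alternatives with adjusted p up to 0.236, and sst1.1 was 3.72-fold higher (adjusted p = 9.87e-05). Of the other calls, those of shisa4, cbsb and tagln2 were lost in 8 of 14 alternatives, those of ccnt1 and srsf6a in 6, those of gnpda2, slc7a8b and kcnh6a in 5, those of gria3a and PKIB (2 of 2) in 4, that of bsg in 3 and those of s1pr1 and fam46bb in 2.

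Of 25 immediate early and heat shock genes 11 rose and 0 fell (17 adjusted over the list alone), with jun 6.46-fold, junbb 5.26-fold and hsp70.1 4.17-fold higher (list adjusted p = 3.92e-34, and adjusted p = 0.0128 with an estimated correlation). Of 30 ER stress genes 7 rose (11 rose and 2 fell adjusted over the list alone), with hspa5 4.33-fold higher, herpud1 at 55.9 ± 12.4 against 12.9 ± 8.35 CPM and hyou1 2.33-fold higher, the last 2 calls lost in 2 and 4 of 14 alternatives (adjusted p = 1.97e-09, and adjusted p = 0.0842 with an estimated correlation). Of 7 delta-cell genes 2 rose, sst1.1 and dkk3b (3.29-fold), and 4 adjusted over the list alone (adjusted p = 1.11e-07, and adjusted p = 0.0842 with an estimated correlation). Of 13 beta-cell genes only ins fell (2 adjusted over the list alone, list adjusted p = 0.123), and mnx1 stood at 34.7 ± 9.26 against 62.2 ± 2.24 CPM (adjusted p = 0.262). Of 20 pan-endocrine genes 3 rose and 0 fell (4 rose and 4 fell adjusted over the list alone, list adjusted p = 0.717, downward with a median of -0.33 and a mean of 0.01): the granins chga (2.41-fold), scg2a (2.97-fold) and scg2b (1.65-fold, lost in 6 of 14 alternatives). The peptide gene pyyb rose 4.94-fold. Of 11 ductal genes clu rose 2.23-fold, a call lost in 8 of 14 alternatives with adjusted p up to 0.231 (6 adjusted over the list alone, list adjusted p = 3.77e-05, and adjusted p = 0.143 with an estimated correlation). Of 77 ribosomal protein genes rpl22l1 fell 2.39-fold, a call lost in 5 of 14 alternatives (26 adjusted over the list alone, list adjusted p = 1.28e-14, and adjusted p = 0.430 with an estimated correlation). The proteasome list was called upward with 0 single genes (adjusted p = 3.56e-05, and adjusted p = 0.430 with an estimated correlation). The remaining tested lists were not called.

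Of the 151 genes, 144 were also called between the single-positive groups, each on the side of sst1.1+. Independent lists would share 3 higher and 0.436 lower genes, and simulated unchanged groups, with at most 4 calls, shared at most 1. Both comparisons share the 2 ins+ libraries, so part of the excess may come from them. With 1 ins+ library for each comparison, 42 of 55 genes (replicate 1 in this comparison) and 76 of 162 (replicate 2) were shared in direction. Without sst1.1+ins+ replicates 1, 2 or 3 the count was 68, 99 or 78, and it was 61 without ins+ replicate 2. It was 774 with DESeq2 (60 false calls in simulated counts against 10), 560 without a low-count filter and 242 at 10 CPM, and limma-voom (4 false calls) called 69 genes higher and 108 lower, the opposite balance.

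No gene passed edgeR's test above or below both single-positive groups. At an unadjusted p under 0.05 in both comparisons, 34 genes lay above and 83 below. In 20 simulations of unchanged groups there were 156 to 196 such genes. The simulations gave all 3 groups 1 mean per gene, while here 662 genes were called between ins+ and sst1.1+. Genes that differ between these groups have less room to lie beyond both, so the smaller count does not show fewer such genes than by chance. DESeq2 called 9 such genes, edgeR without a low-count filter 9 and limma-voom 0. In contrast, 5 genes were called higher than in sst1.1+ and lower than in ins+, and 4 the reverse.

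Calls of sst1.1+ins+, which can miss differences, were counted over the 662 genes called between the single-positive groups. This group was called different from sst1.1+ alone for 25, from ins+ alone for 135, from both for 9 and from neither for 493. On the log2 scale from sst1.1+ (0) to ins+ (1), its median position was 0.546 over the 214 genes at least 2-fold higher in ins+ (quartiles 0.376 and 0.693), and 0.534, 0.513 and 0.533 in its single replicates. Over the 351 genes at least 2-fold higher in sst1.1+ it was 0.271 (quartiles 0.170 and 0.408), and 0.223, 0.306 and 0.292 in the replicates. Among the first set 91 genes lay below 0.5 and 123 above, and among the second 312 below and 39 above. These positions depend on the scale. On the linear scale, over genes of at least 20 CPM in the higher group, the median share of the way to ins+ was 0.349 for 194 genes higher in ins+. It was 0.508 for 261 genes higher in sst1.1+, so the order of the sets reversed. The genes were chosen by the same comparison that sets both ends of the scale. Mixtures simulated at 1 share of 0.491 for all genes gave 0.375 to 0.413 and 0.512 to 0.556. A linear gap of this kind therefore arises without a true difference between the sets.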

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

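In the 14 alternatives where named genes were followed, no called gene turned its sign. The largest rises and falls were chosen with non-overlapping CPM, so leaving out 1 library could hardly turn theirs. The fits with libraries thinned to the smallest total and the counts without stress list genes were chosen after the data were seen. RLE scaling kept 126 and DESeq2 127 of 127 named calls, library totals 119, limma-voom 104 and the fit without ins+ replicate 2 only 76. The counts for ins+ against sst1.1+, sst1.1+ins+ against sst1.1+ and sst1.1+ins+ against ins+ (662, 34 and 151) became 1677, 270 and 774 with DESeq2, whose calls included all of those genes. They became 1276, 229 and 560 without a low-count filter, which also changed the genes tested. At 10 CPM the last 2 were 79 and 242, with limma-voom the second was 99, and with only both groups fitted the first was 412, from fewer libraries. The balance of rises and falls turned with limma-voom, where 42.6, 59.6 and 61% of called genes were lower, against 60, 14.7 and 17.9% with edgeR, and 487 of 662, 27 of 34 and 89 of 151 genes stayed called. Genes above or below both groups numbered 0, but 9 with DESeq2 and 9 without a filter. In simulated counts DESeq2 made 78, 56 and 60 false calls against 13, 7 and 10 with edgeR, but recovered more changed genes at each fold. The cause of the shifts in counts was not tested. Leaving out 1 library gave 330 to 757, 19 to 29 and 61 to 194 calls (where an arm kept 1 ins+ library, it was assumed to vary like the others), 0 to 0 genes beyond both groups, 13 to 15, 10 to 13 and 6 to 8 called lists, and positions of 0.452 to 0.596 and 0.186 to 0.318. The position of ins+-high genes was 0.568 over genes called at 0.01 and 0.501 as a mean over genes of at least 20 CPM, where that of sst1.1+-high genes was 0.333. With an estimated correlation the called lists fell from 13, 13 and 6 to 3, 1 and 1. Over all genes, deviations from group means correlated at -0.0291 to 0.0125 between same-numbered libraries. With so few libraries per group this cannot exclude that the numbers pair the samples, and the labels do not say. A replicate block gave 648, 44 and 181 calls and 0 genes beyond both groups.

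Signs turned, or the value became 0 (adra2b), only for genes that were not called, with these ranges of log2 fold change without 1 library. For ins+ against sst1.1+, sst1.2 ran from -0.430 (without sst1.1+ replicate 2) to 0.138 (without sst1.1+ replicate 1), kif11 from -0.185 (without ins+ replicate 1) to 3.35 (without ins+ replicate 2) and adra2b from 0 (without ins+ replicate 2) to 8.67 (without ins+ replicate 1). For sst1.1+ins+ against sst1.1+, sst1.2 ran from -0.317 (without sst1.1+ins+ replicate 2) to 0.382 (without sst1.1+ replicate 1), and was -0.187 and -0.0742 without sst1.1+ replicates 2 and 3 and -0.156 with limma-voom. There sst2 ran from -0.195 (without sst1.1+ins+ replicate 2) to 1.06 (without sst1.1+ replicate 1), and pdx1 from -0.0820 (without sst1.1+ replicate 3) to 0.192 (without sst1.1+ replicate 1). For sst1.1+ins+ against ins+, sst1.2 ran from -0.0956 (without sst1.1+ins+ replicate 2) to 0.483 (without sst1.1+ins+ replicate 1) and sst2 from -0.797 (without sst1.1+ins+ replicate 2) to 0.0527 (without sst1.1+ins+ replicate 1). Thinning to 16948429 counts, the smallest library, gave 706, 39 and 157 calls.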

Other observations

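The hormone genes gip and ghrl varied widely between libraries of 1 group. These genes were chosen after their values were seen. The incretin gene gip stood at 5060, 11531 and 39.8 CPM in the 3 sst1.1+ins+ libraries, at 5939, 15087 and 4630 in sst1.1+ and at 1932 and 44.2 in ins+. The ghrelin gene ghrl stood at 49.8, 251 and 3947 CPM in sst1.1+ins+, at 201, 82.6 and 2595 in sst1.1+ and at 4794 and 106 in ins+. Neither passed edgeR's test (adjusted p of 0.367 or more in each comparison).

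In the patterns below, the tests of handling, of depth for glucagon genes and of other splits were set before their results were seen, and the others after. The criteria for the mixture and for alpha-cell RNA were first looser, and both explanations passed them. They were made stricter after those values were seen, so neither outcome is a planned test.

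The sst1.1+ins+ libraries lay between both single-positive groups. With hormone and mitochondrial genes out of the totals, all 34 genes called against sst1.1+ stayed called, as did 662 of 662 and 150 of 151 in the other comparisons. Scaled by library totals alone, 33 of 34, 621 of 662 and 141 of 151 stayed called. For these calls, this argues against an effect of these abundant transcripts through the totals. Effects by other routes were not tested and stay open. A mixture of both cell types, or doublets, would give 1 linear share of ins+ RNA for all genes. The median share was 0.349 over 194 genes higher in ins+ and 0.508 over 261 higher in sst1.1+, a difference of -0.160. In 20 mixtures simulated at a fixed share of 0.491, that solved from ins, the difference was -0.162 to -0.115. The simulated shares were 0.375 to 0.413 and 0.512 to 0.556. Other proportions were not simulated, so observed shares below these ranges do not decide against a mixture. The simulated mixtures also gave 137 to 206 calls against sst1.1+, where 34 were seen, and 204 to 304 against ins+, where 151 were seen. The simulations took the observed group means as true, so their excess of calls in both comparisons does not decide against a mixture. The share in the real libraries was 0.491 ± 0.033 (SD, n = 3) from ins, 0.423 ± 0.115 from sst1.1 and 0.565 ± 0.032 from EGFP. A single population carrying both programmes and a mixture cannot be told apart here, because bulk values average over cells and the count of genes outside both groups, 0 with edgeR, was 9 with DESeq2 and 9 without a low-count filter.

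Immediate early and ER stress genes were called lower in ins+ than in both other groups (for ER stress against sst1.1+ins+ adjusted p = 0.0842 with an estimated correlation), while against sst1.1+ only atf3 of their members was called lower in sst1.1+ins+ and both lists lost their call (each adjusted p = 0.0668 with an estimated correlation). A single stressed library was argued against, since without any 1 library the immediate early list kept an adjusted p of at most 2.78e-24 and the ER stress list of at most 4.24e-10 for ins+ against sst1.1+, both at the preset correlation. Handling that differed between whole groups may contribute and cannot be told apart from cell type, because the labels do not say how each group was handled. The median share of the way to ins+ was 0.474 over 25 stress list genes higher in sst1.1+ and 0.510 over the 236 other genes higher there, a difference of -0.0366, which excludes neither. A difference between the cell types themselves stays open and untested.

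Glucagon genes gcga and gcgb were lower in ins+ than in sst1.1+. Depth was argued against, since both stayed called with all libraries thinned to the smallest total (adjusted p of at most 0.00836), and without ins+ replicate 2 the calls were lost (0.0569 and 0.0713) at log2 differences of 1.55 and 1.57, against 1.75 and 2.08 with all libraries. RNA of alpha cells in the libraries is a candidate explanation and would lower the other alpha-cell genes alike. Their median log2 fold change was -1.81 over 5 genes, but they ranged from -3.11 (gip) to 4.64 (ttr, under 4 CPM), with arxa at -2.18 ± 0.61 SE, so the test decides nothing. The labels name no alpha-cell reporter, and a difference between the sorted cells stays open.

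The 6 libraries of sst1.1+ and sst1.1+ins+ can be split 3 against 3 in only 10 ways, too few for a share under 0.05. The real split called 34 genes and every other split 0. It called 13 lists, and the other splits called 2 to 9. At the preset correlation, lists were thus called also in splits that called 0 genes. In each case 1 of 10 splits, the real one, gave as many.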
